A study of Caenorhabditis elegans with 8 samples.

How the data were processed

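The study measured transcript levels in adult Caenorhabditis elegans of the laboratory strain N2 on a 1-colour Affymetrix array. Worms were kept with or without cholesterol, which this nematode cannot synthesise, from hatching, and were moved as young adults to plates with FUDR, a nucleotide analogue used to block progeny. They were then fed or fasted. The labels conflict on the length of the fast: the source names give 24 h and the treatment protocol gives 48 h starting on day 2 of adulthood, so no duration is assumed here. All 8 samples were collected on day 4 of adulthood. Biotin-labelled cRNA was made from 100 ng of total RNA, per the labels' protocols. The 2 arrays of each of the 4 groups are described as independent replicates, with no mention of a shared day.

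The deposited values are one intensity per probe set and array, normalised with RMA (robust multi-array average) per the submitters' processing notes; the version is not given in the sources used here. RMA usually returns log2 values, but the deposited intensities are on a linear scale, with array medians of 66.9 to 71.0 and maxima of 18896.9 to 22352.1. RMA subtracts background, equalises the distributions of the arrays and combines the probes of a set, so differences in total RNA between groups are not visible in these values. No detection call was used, and the number of arrays limits the precision.

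The table held 22625 probe sets. The 77 Affymetrix control probe sets were left out, and 22548 were tested. The platform annotation gave 1 gene symbol to 20766 of them, several to 887 and none to 895. Of those with 1 symbol, 20701 matched the RefSeq gene table of assembly WBcel235 by gene number, which was used for names alone; the build behind the array annotation is not given in the sources used here, so no coordinates are printed. The 1-symbol probe sets stood for 17118 genes, and a gene was represented by its probe set with the highest mean signal.

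Values were transformed as log2(signal + 1), which understates the change of dim genes. A limma model (lmFit and eBayes, version 3.58.1 in R 4.3.3) with 1 mean per group was fitted over all 8 arrays, with 4 residual and 3.37 prior degrees of freedom. All tests were two-sided. P values were adjusted by the Benjamini-Hochberg method over all probe sets of a contrast, and "rose" or "fell" is used for an adjusted p under 0.05. Errors of a log2 change are standard errors of that fit with n = 2 arrays per group. The contrasts were fasted minus fed at each cholesterol state, deprived minus not deprived at each feeding state, the difference of the 2 fasting effects (the interaction), and both averages over 4 against 4 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

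The design, the alternatives, the rule for naming genes and 31 gene lists were fixed before the data were examined. The rule took, in each of the first 5 contrasts, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between the groups compared, up to 4 members of each list with the smallest p, and 18 genes of sterol, fat and DAF-16 biology in every contrast. Lists held DAF-16 targets, gene families and pathways from textbook knowledge, and markers of tissues, germline and embryos; none was chosen on these samples. Some genes sit in more than 1 list: the repressed DAF-16 list shares 2 genes with the vitellogenins and 2 with the intestinal markers, and the intestinal markers share 9 with the lysosomal list. Each list was tested against all other genes with camera at its preset inter-gene correlation of 0.01, adjusted over the 31 lists of a contrast. With a correlation estimated per list, camera called 0 of the 31 lists in each of the 7 contrasts (at an unadjusted p under 0.05, 5, 6, 2, 1, 0, 5 and 3 lists in the order given above), and that p is given beside each list call. In the text, "adjusted over the list alone" means that the Benjamini-Hochberg step ran over the members of the list. Where a list's size is written in full, members past the threshold over all probe sets are given as rose, fell and neither.

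The fits were tested on simulated arrays with 100 probe sets changed 2-fold and 100 changed 4-fold. For fasting with cholesterol, 65% and 97% were recovered with 13 false calls, and for deprivation in fed worms 70% and 99% with 3 false calls. For the interaction, 14% and 84% were recovered with 3 false calls, and for the average fasting effect 86% and 97% with 8 false calls. An intestinal list shifted by -1 log2 was called, and 0 of 24 lists without shared members were. Probe sets were simulated as independent of each other, so this gives no measure of false list calls where genes are correlated.

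The alternatives were the replicate number as a block, cyclic loess between arrays, a shift of each array to an equal median of the third of probe sets that is brightest (the bright-set shift), leaving out the dimmest 40%, and leaving out probe sets whose names end in _s_at or _x_at (their probes match more than 1 transcript or gene). Others were eBayes with trend and robust settings, array weights, log2(signal + 16), a 2-fold minimum, an adjusted p under 0.1, fits of the compared groups alone, all probe sets of a gene averaged, and each array left out in turn. With an array left out, its group keeps 1 array, which is assumed to vary like the other groups, and calls can be lost from the fewer degrees of freedom alone.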

Results

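Transcript levels were measured on 8 arrays of day 4 adult worms in a crossed design with 4 groups of 2 arrays: fed with cholesterol, fasted with cholesterol, fed without cholesterol and fasted without cholesterol. The series title puts the question of how cholesterol bears on the FOXO transcription factor DAF-16 and on the response to fasting, and the design gives the fasting response at each cholesterol state, the effect of deprivation at each feeding state, and the difference between the fasting responses. Whether fasting lasted 24 h or 48 h is left open by the labels. Array medians lay between 66.9 and 71.0 intensity units. Replicates of a group correlated at r = 0.992 to 0.994 across probe sets, and arrays of different groups at 0.972 to 0.992. The first principal component, with 48.3% of the variance, separated fasted from fed worms, and the second, with 21.6%, separated the cholesterol states. Of the 98 largest changes named here, 11 had a group mean below the lower quartile of all log2 values, 4.69, where changes are understated and ranks uncertain; they belong to T22F3.11, F40G12.5, gst-14, D1086.3, R07C12.1, lips-14 and asm-2.

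In worms given cholesterol, fasting lowered sysm-1 and the lysozyme genes ilys-5 and lys-2 and raised adh-1, acs-2 and aqp-1. The largest fall was that of sysm-1 (-6.61 ± 0.18, adjusted p = 1.05e-05), from a log2 signal of 12.20 ± 0.23 (SD, n = 2) to 5.59 ± 0.26. The invertebrate-type lysozyme ilys-5 changed by -5.38 ± 0.15 and the DAF-16-repressed gene dod-19 by -5.09 ± 0.28. Each ilys-5 probe set has a name ending in _s_at or _x_at, so its signal may include other genes. The largest rise was that of adh-1, an alcohol dehydrogenase (4.02 ± 0.30, adjusted p = 0.000564), which was 16.3-fold higher in fasted worms. Next came acs-2, an acyl-CoA synthetase of mitochondrial fatty acid oxidation (3.85 ± 0.26, adjusted p = 0.000405), and aqp-1, an aquaglyceroporin (3.82 ± 0.19, adjusted p = 0.00011). A second acs-2 probe set, which does not represent the gene, rose by 4.76 (adjusted p = 3.81e-05), more than adh-1. In all, 1164 of 22548 probe sets passed, 457 higher (405 genes) and 707 lower (605 genes), and 550 of them changed at least 2-fold.

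The other named rises with cholesterol present were the lysozyme ilys-3 (3.72), T22F3.11 (3.70, with an uncalled second probe set at 2.25), the fatty acid and retinol binding protein gene far-7 (3.10), the small heat shock genes hsp-12.3 (2.95) and hsp-12.6 (2.66), F40G12.5 (2.61) and C23G10.11 (2.45). The other named falls were bcf-1 (-5.26), C14C6.5 (-4.98), Y105C5B.15 (-4.80), mbug-1 (-4.79), ctsa-1.2 (-4.75), hrg-11.2 (-4.72) and D1086.3 (-4.54).

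Among 55 lysozyme, saposin-like and other antimicrobial genes, 4 rose, 20 fell and 31 did neither (4 rose and 24 fell adjusted over the list alone), with lys-2 at -3.30 ± 0.14 and cnc-7 at -3.97 ± 0.20 among the falls and ilys-3 among the rises. The antimicrobial list had a camera adjusted p = 2.81e-11, and adjusted p = 0.128 with an estimated correlation. Of 45 genes of lysosomal proteases and the proton pump, 1 rose, 9 fell and 35 did neither (3 rose and 15 fell adjusted over the list alone), with the cathepsin B-like genes cpr-9 at -3.08 lower and cpr-2 at 1.103 higher. The lysosomal list had a camera adjusted p = 2.18e-05, and adjusted p = 0.128 with an estimated correlation. The cuticle collagens moved down: of 146, 0 rose, 20 fell and 126 did neither (0 rose and 37 fell adjusted over the list alone), with col-183 at -3.51. The collagen list had a camera adjusted p = 2.1e-11, and adjusted p = 0.472 with an estimated correlation. Of 24 body wall muscle genes, 0 rose, 4 fell and 20 did neither (0 rose and 7 fell adjusted over the list alone), among them the troponin I gene unc-27 at -1.28. The muscle list had a camera adjusted p = 2.14e-05, and adjusted p = 0.472 with an estimated correlation. The intestinal markers included 26 measured genes, of which 1 rose, 8 fell and 17 did neither (2 rose and 13 fell adjusted over the list alone), with the transporter pgp-1 at -2.18 and the microvillar actin act-5 at -1.51. The intestinal list had a camera adjusted p = 6.48e-07, and adjusted p = 0.227 with an estimated correlation. Their median of -0.54 stood beside the falls of the lysosomal list, which holds 9 of the same genes, and of the antimicrobial list.

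The vitellogenin vit-1 fell (-2.27 ± 0.21, adjusted p = 0.00141), and of 5 vitellogenins 0 rose, 1 fell and 4 did neither (0 rose and 4 fell adjusted over the list alone). The vitellogenin list had a camera adjusted p = 0.000277, and adjusted p = 0.225 with an estimated correlation. The probe sets of vit-4, vit-5 and vit-6 lay above the 99th percentile of all values, 12.73, in all 4 groups, near the top of the scale; a dimmer vit-4 probe set changed by -1.25 where the brightest changed by -0.31. The stearoyl-CoA desaturase fat-7 fell (-2.34 ± 0.30, adjusted p = 0.0066). Of 9 fatty acid binding proteins, 0 rose, 2 fell and 7 did neither (0 rose and 4 fell adjusted over the list alone), with lbp-8 at -1.20. The fatty acid binding list had a camera adjusted p = 0.00262, and adjusted p = 0.352 with an estimated correlation. Of 37 fatty acid oxidation genes, 2 rose, 0 fell and 35 did neither (2 rose and 0 fell adjusted over the list alone): acs-2 and the hydroxyacyl-CoA dehydrogenase hacd-1 (1.75); the list did not pass (camera adjusted p = 0.984). Of 42 respiratory chain and ATP synthase genes, 1 rose, 0 fell and 41 did neither (1 rose and 0 fell adjusted over the list alone), and the list moved up with a median of 0.30. The respiratory chain list had a camera adjusted p = 0.000101, and adjusted p = 0.453 with an estimated correlation. UDP-glucuronosyltransferases moved down with a median of -0.03, which turned to 0.06 after the bright-set shift, and ugt-63 at -2.91. Of 64, 2 rose, 11 fell and 51 did neither (3 rose and 13 fell adjusted over the list alone). The UDP-glucuronosyltransferase list had a camera adjusted p = 0.00199, and adjusted p = 0.453 with an estimated correlation. Glutathione S-transferases moved down with a median of -0.06, which turned to 0.03 after that shift, and gst-10 at -2.94. Of 45, 2 rose, 6 fell and 37 did neither (3 rose and 8 fell adjusted over the list alone). The glutathione S-transferase list had a camera adjusted p = 0.0141, and adjusted p = 0.308 with an estimated correlation.

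The remaining lists past the threshold with cholesterol present were tissue and stage markers and DAF-16 targets. Neuronal genes moved up with a median of 0.21. Of 106, 6 rose, 2 fell and 98 did neither (18 rose and 7 fell adjusted over the list alone). The neuronal list had a camera adjusted p = 0.0141, and adjusted p = 0.778 with an estimated correlation. Zygotic embryo genes moved up with a median of 0.20. Of 45, 8 rose, 1 fell and 36 did neither (12 rose and 1 fell adjusted over the list alone). The zygotic embryo list had a camera adjusted p = 0.00109, and adjusted p = 0.472 with an estimated correlation. Oocyte genes moved down with a median of -0.14. Of 48, 0 rose, 0 fell and 48 did neither (0 rose and 0 fell adjusted over the list alone). The oocyte list had a camera adjusted p = 0.00387, and adjusted p = 0.647 with an estimated correlation. Of 16 DAF-16-repressed genes, 1 rose, 6 fell and 9 did neither (1 rose and 9 fell adjusted over the list alone), including the insulin-like peptide gene ins-7 at -3.89 and dod-24 at -3.001. The DAF-16-repressed list had a camera adjusted p = 4.2e-06, and adjusted p = 0.128 with an estimated correlation. Of 20 DAF-16-activated genes, 3 rose, 2 fell and 15 did neither (5 rose and 2 fell adjusted over the list alone): aqp-1, hsp-12.6 and the glyoxylate cycle gene icl-1 (1.31 ± 0.16, adjusted p = 0.00511) rose, and lys-7 (-2.26) fell; that list did not pass (camera adjusted p = 0.161).

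Of the 14 list calls, 11 held without each array in turn. Calls were lost for the other 3, here with the highest adjusted p of each. With the fasted undeprived replicate 1 left out, the neuronal (adjusted p = 0.199) and oocyte (adjusted p = 0.321) lists did not pass. With the fed undeprived replicate 2 left out, the glutathione S-transferase (adjusted p = 0.0864) list did not pass. More than 1 array, in the number given, ended the call when left out for neuronal (2).

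The limma count of 1164 was 381 and 430 without replicate 1 or 2 of the fed worms given cholesterol, 453 and 506 without replicate 1 or 2 of their fasted counterparts, and 761 without either fed array of the deprived worms. Of the 20 largest changes, 17 passed without each of the 8 arrays in turn, and the share of higher probe sets, 39.3% here, was 60.9% after the bright-set shift.

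Without cholesterol, fasting again lowered sysm-1, ilys-5 and lys-2, while adh-1 (-0.07 ± 0.30) and acs-2 (0.67 ± 0.26) did not pass. The largest fall was that of ilys-5 (-6.92 ± 0.15, adjusted p = 2.48e-06), from 13.36 ± 0.08 (SD, n = 2) to 6.44 ± 0.01, followed by sysm-1 (-6.64 ± 0.18). The ilys-5 probe sets that do not represent the gene changed by -7.02 and -7.88, and they too may pick up other genes. The lysozyme lys-2 fell by 5.15 on the log2 scale (-5.15 ± 0.14, adjusted p = 5.13e-06). The largest rises were those of ilys-3 (2.51 ± 0.29, adjusted p = 0.00552) and ftn-1, a ferritin (2.44 ± 0.33, adjusted p = 0.0114). In all, 656 probe sets passed, 223 higher (201 genes) and 433 lower (371 genes), and 408 changed at least 2-fold.

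Further named rises without cholesterol were ilys-2 (2.31), the glutathione S-transferase gst-14 (2.16), F40G12.5 (1.99), C10C5.3 (1.95), hacd-1 (1.94), ins-22 (1.84), the linker histone hil-1 (1.78) and srap-1 (1.77, with an uncalled second probe set at 1.46). Further named falls were C17H12.8 (-6.29), hrg-11.2 (-5.98), bcf-1 (-5.37), Y105C5B.15 (-5.36), ctsa-1.2 (-5.32), D1086.3 (-5.13) and C14C6.5 (-5.09).

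In deprived worms, 20 of 55 antimicrobial genes fell, 2 rose and 33 did neither (3 rose and 22 fell adjusted over the list alone), with lys-1 at -3.42 and lys-8 at -3.12. The antimicrobial list had a camera adjusted p = 2.39e-09, and adjusted p = 0.118 with an estimated correlation. Of 45 lysosomal protease and proton pump genes, 0 rose, 11 fell and 34 did neither (1 rose and 18 fell adjusted over the list alone), with the aspartyl proteases asp-1 at -3.02 and asp-3 at -2.43. The lysosomal list had a camera adjusted p = 2.26e-07, and adjusted p = 0.0997 with an estimated correlation. Of 220 C-type lectins, 2 rose, 23 fell and 195 did neither (2 rose and 25 fell adjusted over the list alone), with clec-41 at -4.47. The C-type lectin list had a camera adjusted p = 8.66e-07, and adjusted p = 0.217 with an estimated correlation. With cholesterol 18 fell and 1 rose, and the list, whose median was 0.10, did not pass (camera adjusted p = 0.984). Of 29 lipases in deprived worms, 0 rose, 5 fell and 24 did neither (1 rose and 6 fell adjusted over the list alone), with lips-11 at -4.87 and the lysosomal lipase lipl-1 at -2.77. The lipase list had a camera adjusted p = 0.0157, and adjusted p = 0.207 with an estimated correlation. Intestinal markers had a median of -0.79: of 26, 0 rose, 9 fell and 17 did neither (0 rose and 17 fell adjusted over the list alone). The intestinal list had a camera adjusted p = 1.31e-11, and adjusted p = 0.118 with an estimated correlation.

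Collagens moved down with a median of -0.31. Of 146, 0 rose, 8 fell and 138 did neither (1 rose and 48 fell adjusted over the list alone). The collagen list had a camera adjusted p = 8.02e-19, and adjusted p = 0.297 with an estimated correlation. Body wall muscle genes had 5 falls among 24 (0 rose and 11 fell adjusted over the list alone), with the troponin T gene tnt-2 at -1.90. The muscle list had a camera adjusted p = 1.75e-06, and adjusted p = 0.297 with an estimated correlation. Of 5 vitellogenins, 0 rose, 3 fell and 2 did neither (0 rose and 3 fell adjusted over the list alone). The vitellogenin list had a camera adjusted p = 0.00036, and adjusted p = 0.201 with an estimated correlation. DAF-16-repressed genes moved down with a median of -0.37. Of 16, 0 rose, 6 fell and 10 did neither (0 rose and 8 fell adjusted over the list alone). The DAF-16-repressed list had a camera adjusted p = 2.74e-07, and adjusted p = 0.0997 with an estimated correlation. Fatty acid binding proteins moved down with a median of -0.32. Of 9, 0 rose, 0 fell and 9 did neither (0 rose and 2 fell adjusted over the list alone). The fatty acid binding list had a camera adjusted p = 0.0156, and adjusted p = 0.297 with an estimated correlation. Respiratory chain genes moved up with a median of 0.17. Of 42, 0 rose, 0 fell and 42 did neither (0 rose and 0 fell adjusted over the list alone). The respiratory chain list had a camera adjusted p = 4.82e-05, and adjusted p = 0.297 with an estimated correlation. Neuronal genes moved up with a median of 0.14. Of 106, 2 rose and 0 fell (7 rose and 1 fell adjusted over the list alone). The neuronal list had a camera adjusted p = 5.62e-05, and adjusted p = 0.419 with an estimated correlation. Zygotic embryo genes moved up with a median of 0.15. Of 45, 2 rose, 0 fell and 43 did neither (6 rose and 1 fell adjusted over the list alone). The zygotic embryo list had a camera adjusted p = 2.45e-05, and adjusted p = 0.297 with an estimated correlation. Autophagy genes moved up with a median of 0.18. Of 28, 0 rose, 0 fell and 28 did neither (3 rose and 0 fell adjusted over the list alone). The autophagy list had a camera adjusted p = 0.000435, and adjusted p = 0.217 with an estimated correlation. Insulin, TOR and AMPK signalling genes moved up with a median of 0.16, the insulin receptor substrate gene ist-1 at 0.97 and the kinase pdk-1 at 0.76. Of 44, 2 rose, 0 fell and 42 did neither (3 rose and 0 fell adjusted over the list alone). The signalling list had a camera adjusted p = 0.00328, and adjusted p = 0.419 with an estimated correlation. F-box and Skp1-related genes moved up with a median of 0.05. Of 329, 7 rose, 3 fell and 319 did neither (7 rose and 3 fell adjusted over the list alone). The F-box list had a camera adjusted p = 0.00405, and adjusted p = 0.297 with an estimated correlation.

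Of the 16 list calls, 15 held without each array in turn. Calls were lost for the other 1, here with the highest adjusted p of each. With the fed deprived replicate 1 left out, the fatty acid binding (adjusted p = 0.156) list did not pass. More than 1 array, in the number given, ended the call when left out for fatty acid binding (2).

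The limma count of 656 was 284 and 258 without replicate 1 or 2 of the fed deprived worms and 274 without replicate 2 of the fasted deprived worms. Of the 20 largest changes, 13 passed without each of the 8 arrays in turn.

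**Figure D1:**
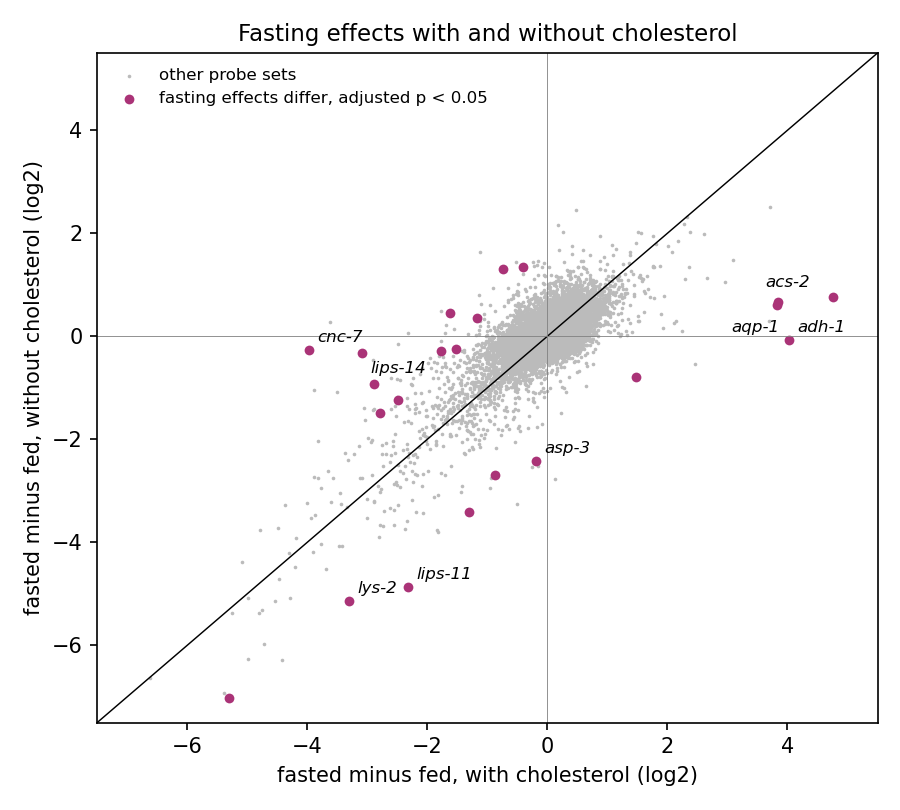
Each point is 1 of 22548 probe sets, with the log2 change from fed to fasted worms given cholesterol on the x axis and without cholesterol on the y axis, the mean of 2 arrays against 2 on each axis, and the diagonal marking equal effects. The 22 probe sets whose fasting effects differed at an adjusted p under 0.05 are larger and coloured, with acs-2, aqp-1 and adh-1 at right, changed by 3.85, 3.82 and 4.02 with cholesterol.

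The 2 fasting responses, which share no array, were compared directly. Across probe sets their log2 changes correlated at Pearson r = 0.71 (Spearman 0.42), and at 0.61 and 0.72 within the arrays of replicate number 1 and number 2; genes are not independent replicates, so no p is attached. Both responses called 100 probe sets higher, against 4.52 for independent lists, and 323 lower, against 13.6, and 4 were called in opposite directions. The calls share 1 estimate of the spread per probe set, so they can coincide more often than independent lists would. Among the 2398 probe sets past the threshold for the average fasting effect, the median response was 0.66 with and 0.59 without cholesterol, and 60.1% were smaller without it. The median difference of -0.09 did not pass fry's test. Over the left-out arrays it lay between -0.17 (without replicate 2 of the fasted undeprived worms) and 0.07 (without replicate 1 of the fasted deprived worms), and it passed in 1 of these fits, without replicate 2 of the fasted deprived worms (-0.13).

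Cholesterol deprivation of fed worms raised acs-2 and adh-1, which fasting also raised in undeprived worms, and lowered cnc-7 and fat-7. The largest rise was that of T22F3.11 (4.88 ± 0.66, adjusted p = 0.021; an uncalled second probe set stood at 3.03). Also higher were C23G10.11 (4.23), acs-2 (3.33 ± 0.26, adjusted p = 0.0044) and adh-1 (3.16 ± 0.30, adjusted p = 0.00627), which reached log2 signals of 10.59 ± 0.53 and 11.61 ± 0.09 (SD, n = 2) without food being withdrawn. The largest fall was that of H39E23.3 (-4.07 ± 0.41, adjusted p = 0.00855), followed by the caenacin-type antimicrobial peptide gene cnc-7 (-3.31 ± 0.20, adjusted p = 0.00174) and the collagen gene col-183 (-3.31 ± 0.35, adjusted p = 0.00937). In all, 273 probe sets passed, 116 higher (105 genes) and 157 lower (131 genes), and 183 changed at least 2-fold.

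Other named rises in fed deprived worms were R07C12.1 (3.22), C35C5.8 (3.06), best-1 (2.92), F19C7.2 (2.90), F46C5.1 (2.68) and the lipase-like gene lips-11 (2.47). Other named falls were pud-3 (-3.10), pud-4 (-3.08), ftn-1 (-3.04), T22B7.7 (-3.04), lips-14 (-3.01), the collagen gene dpy-14 (-2.76) and clec-196 (-2.52). The desaturase fat-7 fell (-2.45 ± 0.30, adjusted p = 0.015), as did vit-1 (-1.51 ± 0.21, adjusted p = 0.0225), and the intestinal peptide transporter pept-1 rose (1.78 ± 0.12, adjusted p = 0.00232).

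In fed worms the deprivation lists held few members past the threshold singly. Of 55 antimicrobial genes, 3 rose, 6 fell and 46 did neither (8 rose and 11 fell adjusted over the list alone), with irg-5 at -2.25 and spp-31 at 1.13. The antimicrobial list had a camera adjusted p = 0.00599, and adjusted p = 0.469 with an estimated correlation. Of 20 DAF-16-activated genes, 1 rose, 1 fell and 18 did neither (2 rose and 5 fell adjusted over the list alone): aqp-1 rose (2.07 ± 0.19), hsp-16.2 fell (-1.96 ± 0.29), and the median was -0.49. The DAF-16-activated list had a camera adjusted p = 0.00406, and adjusted p = 0.469 with an estimated correlation. UDP-glucuronosyltransferases had 4 falls and 0 rises among 64 (3 rose and 10 fell adjusted over the list alone), with ugt-41 at -1.66. The UDP-glucuronosyltransferase list had a camera adjusted p = 0.00236, and adjusted p = 0.469 with an estimated correlation. F-box and Skp1-related genes had 6 falls and 2 rises among 329 (6 rose and 24 fell adjusted over the list alone). The F-box list had a camera adjusted p = 0.000406, and adjusted p = 0.469 with an estimated correlation. Fatty acid synthesis genes moved down with a median of -0.15. Of 24, 0 rose, 1 fell and 23 did neither (0 rose and 4 fell adjusted over the list alone). The fatty acid synthesis list had a camera adjusted p = 0.00501, and adjusted p = 0.469 with an estimated correlation. Vitellogenins moved down with a median of -0.17. Of 5, 0 rose, 1 fell and 4 did neither (0 rose and 2 fell adjusted over the list alone). The vitellogenin list had a camera adjusted p = 0.00236, and adjusted p = 0.469 with an estimated correlation. Body wall muscle genes moved down with a median of -0.23. Of 24, 0 rose, 1 fell and 23 did neither (0 rose and 1 fell adjusted over the list alone). The muscle list had a camera adjusted p = 0.00501, and adjusted p = 0.516 with an estimated correlation. Zygotic embryo genes moved down with a median of -0.16. Of 45, 0 rose, 2 fell and 43 did neither (0 rose and 11 fell adjusted over the list alone). The zygotic embryo list had a camera adjusted p = 7.18e-05, and adjusted p = 0.469 with an estimated correlation. Neuronal genes moved up with a median of 0.18. Of 106, 0 rose, 0 fell and 106 did neither (0 rose and 0 fell adjusted over the list alone). The neuronal list had a camera adjusted p = 0.000949, and adjusted p = 0.516 with an estimated correlation. Pharyngeal genes moved up with a median of 0.17. Of 72, 3 rose, 0 fell and 69 did neither (3 rose and 0 fell adjusted over the list alone). The pharyngeal list had a camera adjusted p = 0.0101, and adjusted p = 0.469 with an estimated correlation. Respiratory chain genes moved up with a median of 0.14. Of 42, 0 rose, 0 fell and 42 did neither (0 rose and 0 fell adjusted over the list alone). The respiratory chain list had a camera adjusted p = 0.00606, and adjusted p = 0.476 with an estimated correlation.

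For 6 further lists past the threshold in fed deprived worms the sign of the median or the call changed under another scaling. Collagens moved down with a median of -0.01, which was 0.02 after the bright-set shift. Of 146, 0 rose, 3 fell and 143 did neither (0 rose and 3 fell adjusted over the list alone). The collagen list had a camera adjusted p = 0.0471, and adjusted p = 0.806 with an estimated correlation. Sperm genes moved down with a median of -0.01, which was 0.02 after that shift. Of 66, 0 rose, 0 fell and 66 did neither (0 rose and 0 fell adjusted over the list alone). The sperm list had a camera adjusted p = 0.017, and adjusted p = 0.516 with an estimated correlation. Cytosolic ribosomal proteins moved up with a median of 0.10, but -0.05 after cyclic loess (adjusted p = 0.206). Of 76, 0 rose, 0 fell and 76 did neither (0 rose and 0 fell adjusted over the list alone). The ribosomal list had a camera adjusted p = 0.00599, and adjusted p = 0.659 with an estimated correlation. Glyoxylate and trehalose genes moved down with a median of -0.18, and -0.20 after cyclic loess, where the list did not pass (adjusted p = 0.0642). Of 16, 0 rose, 0 fell and 16 did neither (1 rose and 1 fell adjusted over the list alone). The glyoxylate list had a camera adjusted p = 0.0275, and adjusted p = 0.469 with an estimated correlation. Autophagy genes moved down with a median of -0.03, and -0.07 after cyclic loess, where the list did not pass (adjusted p = 0.137). Of 28, 0 rose, 0 fell and 28 did neither (0 rose and 0 fell adjusted over the list alone). The autophagy list had a camera adjusted p = 0.0471, and adjusted p = 0.469 with an estimated correlation. C-type lectins moved up with a median of 0.09, and 0.02 after cyclic loess, where the list did not pass (adjusted p = 0.242). Of 220, 3 rose, 3 fell and 214 did neither (6 rose and 5 fell adjusted over the list alone). The C-type lectin list had a camera adjusted p = 0.0473, and adjusted p = 0.516 with an estimated correlation. With log2(signal + 16), collagens, autophagy genes and C-type lectins did not pass (adjusted p = 0.0569, 0.053 and 0.0574).

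Of the 17 list calls, 5 held without each array in turn. Calls were lost for the other 12, here with the highest adjusted p of each. With the fed undeprived replicate 1 left out, the autophagy (adjusted p = 0.141), C-type lectin (adjusted p = 0.244), DAF-16-activated (adjusted p = 0.123), glyoxylate (adjusted p = 0.254) and sperm (adjusted p = 0.634) lists did not pass. With the fed undeprived replicate 2 left out, the muscle (adjusted p = 0.0769), ribosomal (adjusted p = 0.457) and respiratory chain (adjusted p = 0.136) lists did not pass. With the fed deprived replicate 1 left out, the neuronal (adjusted p = 0.188) and pharyngeal (adjusted p = 0.0666) lists did not pass. With the fed deprived replicate 2 left out, the collagen (adjusted p = 0.181) and antimicrobial (adjusted p = 0.0977) lists did not pass. More than 1 array, in the number given, ended the call when left out for autophagy (6), muscle (2), C-type lectin (5), collagen (3), DAF-16-activated (2), glyoxylate (2), neuronal (2), sperm (2).

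The limma count of 273 was 25 and 78 without replicate 1 or 2 of the fed worms given cholesterol, 31 and 77 without replicate 1 or 2 of the fed deprived worms, and 179 without either fasted array of the undeprived worms. Of the 20 largest changes, 6 passed without each of the 8 arrays in turn: acs-2, R07C12.1, lips-11, cnc-7, lips-14 and dpy-14.

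In fasted worms, deprivation lowered lipl-1, a lysosomal lipase, asp-3, an aspartyl protease, and lys-2, a lysozyme, and raised cyp-13A5 and 3 transthyretin-related genes. The largest fall was that of lipl-1 (-3.61 ± 0.33, adjusted p = 0.0043), from a log2 signal of 8.60 ± 0.65 (SD, n = 2) to 4.99 ± 0.47. The DAF-16 target dod-3 (-3.05 ± 0.42, adjusted p = 0.0235), lys-2 (-2.76 ± 0.14, adjusted p = 0.000485), F42A10.7 (-2.63) and asp-3 (-2.62 ± 0.15, adjusted p = 0.000787) followed, then the sphingolipid hydrolases asah-1, an acid ceramidase (-2.60), and asm-2, an acid sphingomyelinase (-2.52). The largest rises were those of R07C12.1 (4.14 ± 0.20, adjusted p = 0.000485), from a mean of 4.11 that lies below the lower quartile of 4.69, and the cytochrome P450 gene cyp-13A5 (4.104 ± 0.32, adjusted p = 0.00239). In all, 249 probe sets passed, 155 higher (136 genes) and 94 lower (82 genes), and 166 changed at least 2-fold.

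Other named rises in fasted deprived worms were F14H12.3 (3.64), srlf-3 (3.23), ins-7 (2.92), Y37H2A.14 (2.84), the transthyretin-related genes ttr-29 (2.69), ttr-23 (2.68) and ttr-21 (2.63), and T05E12.3 (2.57). Other named falls were hsp-12.3 (-2.42), clec-61 (-2.26) and T21H3.1 (-2.24).

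Of 45 lysosomal protease and proton pump genes in fasted worms, 0 rose, 4 fell and 41 did neither (2 rose and 10 fell adjusted over the list alone), with asp-13 at -1.61 and asp-1 at -1.28. The lysosomal list had a camera adjusted p = 0.0374, and adjusted p = 0.441 with an estimated correlation. Of 29 lipases, 0 rose, 3 fell and 26 did neither (0 rose and 5 fell adjusted over the list alone): lipl-1, lipl-2 (-1.67) and lipl-5 (-1.48). The lipase list had a camera adjusted p = 0.0165, and adjusted p = 0.441 with an estimated correlation. Of 55 antimicrobial genes, 4 rose, 7 fell and 44 did neither (7 rose and 12 fell adjusted over the list alone), with ilys-5 at -2.14 and lys-1 at -2.05; the list did not pass (camera adjusted p = 0.272). Intestinal markers had a median of -0.08 and did not pass (camera adjusted p = 0.657): of 26, 1 rose, 2 fell and 23 did neither (3 rose and 5 fell adjusted over the list alone). Of 20 DAF-16-activated genes, 0 rose, 3 fell and 17 did neither (0 rose and 8 fell adjusted over the list alone), with a median of -0.79. Those that fell were dod-3, dod-6 (-2.12) and aqp-1 (-1.14). Each of these 3 calls was lost in fits that left out an array. The log2 changes there were -3.28 to -2.81 for dod-3, -2.44 to -1.79 for dod-6 and -1.37 to -0.91 for aqp-1. The DAF-16-activated list had a camera adjusted p = 8.55e-06, and adjusted p = 0.441 with an estimated correlation. C-type lectins had 6 falls and 2 rises among 220 (4 rose and 11 fell adjusted over the list alone). The C-type lectin list had a camera adjusted p = 0.000367, and adjusted p = 0.441 with an estimated correlation. Fatty acid synthesis genes moved down with a median of -0.18, with the desaturase fat-3 at -1.37. Of 24, 0 rose, 1 fell and 23 did neither (1 rose and 6 fell adjusted over the list alone). The fatty acid synthesis list had a camera adjusted p = 0.0165, and adjusted p = 0.441 with an estimated correlation. Vitellogenins moved down with a median of -0.47, the value of vit-4, a probe set near the top of the scale. Of 5, 0 rose, 0 fell and 5 did neither (0 rose and 3 fell adjusted over the list alone). The vitellogenin list had a camera adjusted p = 0.0339, and adjusted p = 0.441 with an estimated correlation. Glyoxylate and trehalose genes moved down with a median of -0.28. Of 16, 0 rose, 1 fell and 15 did neither (0 rose and 2 fell adjusted over the list alone). The glyoxylate list had a camera adjusted p = 0.0165, and adjusted p = 0.441 with an estimated correlation. Zygotic embryo genes moved down with a median of -0.33. Of 45, 0 rose, 0 fell and 45 did neither (0 rose and 0 fell adjusted over the list alone). The zygotic embryo list had a camera adjusted p = 8.55e-06, and adjusted p = 0.441 with an estimated correlation.

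Neuronal genes moved up with a median of 0.16. Of 106, 2 rose and 0 fell (4 rose and 0 fell adjusted over the list alone). The neuronal list had a camera adjusted p = 8.55e-06, and adjusted p = 0.575 with an estimated correlation. Insulin, TOR and AMPK signalling genes moved up with a median of 0.13. Of 44, 0 rose, 0 fell and 44 did neither (5 rose and 0 fell adjusted over the list alone). The signalling list had a camera adjusted p = 0.000142, and adjusted p = 0.445 with an estimated correlation. Ribosomal proteins moved up with a median of 0.09, but did not pass after cyclic loess (median 0.02, adjusted p = 0.456). Of 76, 0 rose, 0 fell and 76 did neither (0 rose and 0 fell adjusted over the list alone). The ribosomal list had a camera adjusted p = 4.29e-05, and adjusted p = 0.632 with an estimated correlation. Oocyte genes moved up with a median of 0.06, but had -0.02 after cyclic loess (adjusted p = 0.918). Of 48, 0 rose, 0 fell and 48 did neither (0 rose and 0 fell adjusted over the list alone). The oocyte list had a camera adjusted p = 0.0109, and adjusted p = 0.638 with an estimated correlation. UDP-glucuronosyltransferases moved up with a median of 0.04, but had -0.01 after the bright-set shift. Of 64, 2 rose, 2 fell and 60 did neither (7 rose and 3 fell adjusted over the list alone). The UDP-glucuronosyltransferase list had a camera adjusted p = 0.0252, and adjusted p = 0.593 with an estimated correlation. F-box genes moved down with a median of -0.12, and -0.04 after cyclic loess, where the list did not pass (adjusted p = 0.33). Of 329, 3 rose, 0 fell and 326 did neither (3 rose and 0 fell adjusted over the list alone). The F-box list had a camera adjusted p = 0.0374, and adjusted p = 0.593 with an estimated correlation. Body wall muscle genes moved down with a median of -0.33, with unc-27 at -1.30 and the titin-like ttn-1 higher at 1.03. Of 24, 1 rose, 4 fell and 19 did neither (1 rose and 8 fell adjusted over the list alone). The muscle list had a camera adjusted p = 0.00661, and adjusted p = 0.632 with an estimated correlation. Without the _s_at and _x_at probe sets the muscle median was -0.04 and camera's direction turned (adjusted p = 0.875). Collagens moved down with a median of -0.14. Of 146, 0 rose, 0 fell and 146 did neither (0 rose and 0 fell adjusted over the list alone). The collagen list had a camera adjusted p = 0.00209, and adjusted p = 0.664 with an estimated correlation. Their median was 0.03 without replicate 2 of the fasted deprived worms (adjusted p = 0.85) and -0.02 without replicate 1 of the fasted undeprived worms (adjusted p = 0.859).

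Of the 16 list calls, 7 held without each array in turn. Calls were lost for the other 9, here with the highest adjusted p of each. With the fasted undeprived replicate 1 left out, the collagen (adjusted p = 0.859) and oocyte (adjusted p = 0.786) lists did not pass. With the fasted undeprived replicate 2 left out, the fatty acid synthesis (adjusted p = 0.161), glyoxylate (adjusted p = 0.0714), lysosomal (adjusted p = 0.135) and vitellogenin (adjusted p = 0.126) lists did not pass. With the fasted deprived replicate 1 left out, the F-box (adjusted p = 0.369) and UDP-glucuronosyltransferase (adjusted p = 0.34) lists did not pass. With the fasted deprived replicate 2 left out, the muscle (adjusted p = 0.175) list did not pass. More than 1 array, in the number given, ended the call when left out for muscle (2), collagen (2), F-box (3), fatty acid synthesis (2), oocyte (2), UDP-glucuronosyltransferase (2), vitellogenin (2).

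The limma count of 249 was lower without each array: 61 and 110 without replicate 1 or 2 of the fasted worms given cholesterol, 91 and 157 without replicate 1 or 2 of the fasted deprived worms, 150 without either fed array of the undeprived worms and 156 without either fed array of the deprived worms. Of the 20 largest changes, 13 passed without each of the 8 arrays in turn. The deprivation effects in fed and in fasted worms share no array, and they correlated at r = 0.45 across probe sets (0.41 and 0.37 within replicate numbers 1 and 2). They had 59 higher calls in common, against 0.797 for independent lists, 13 lower, against 0.655, and 3 in opposite directions. These calls too share 1 estimate of the spread per probe set.

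**Figure D2:**
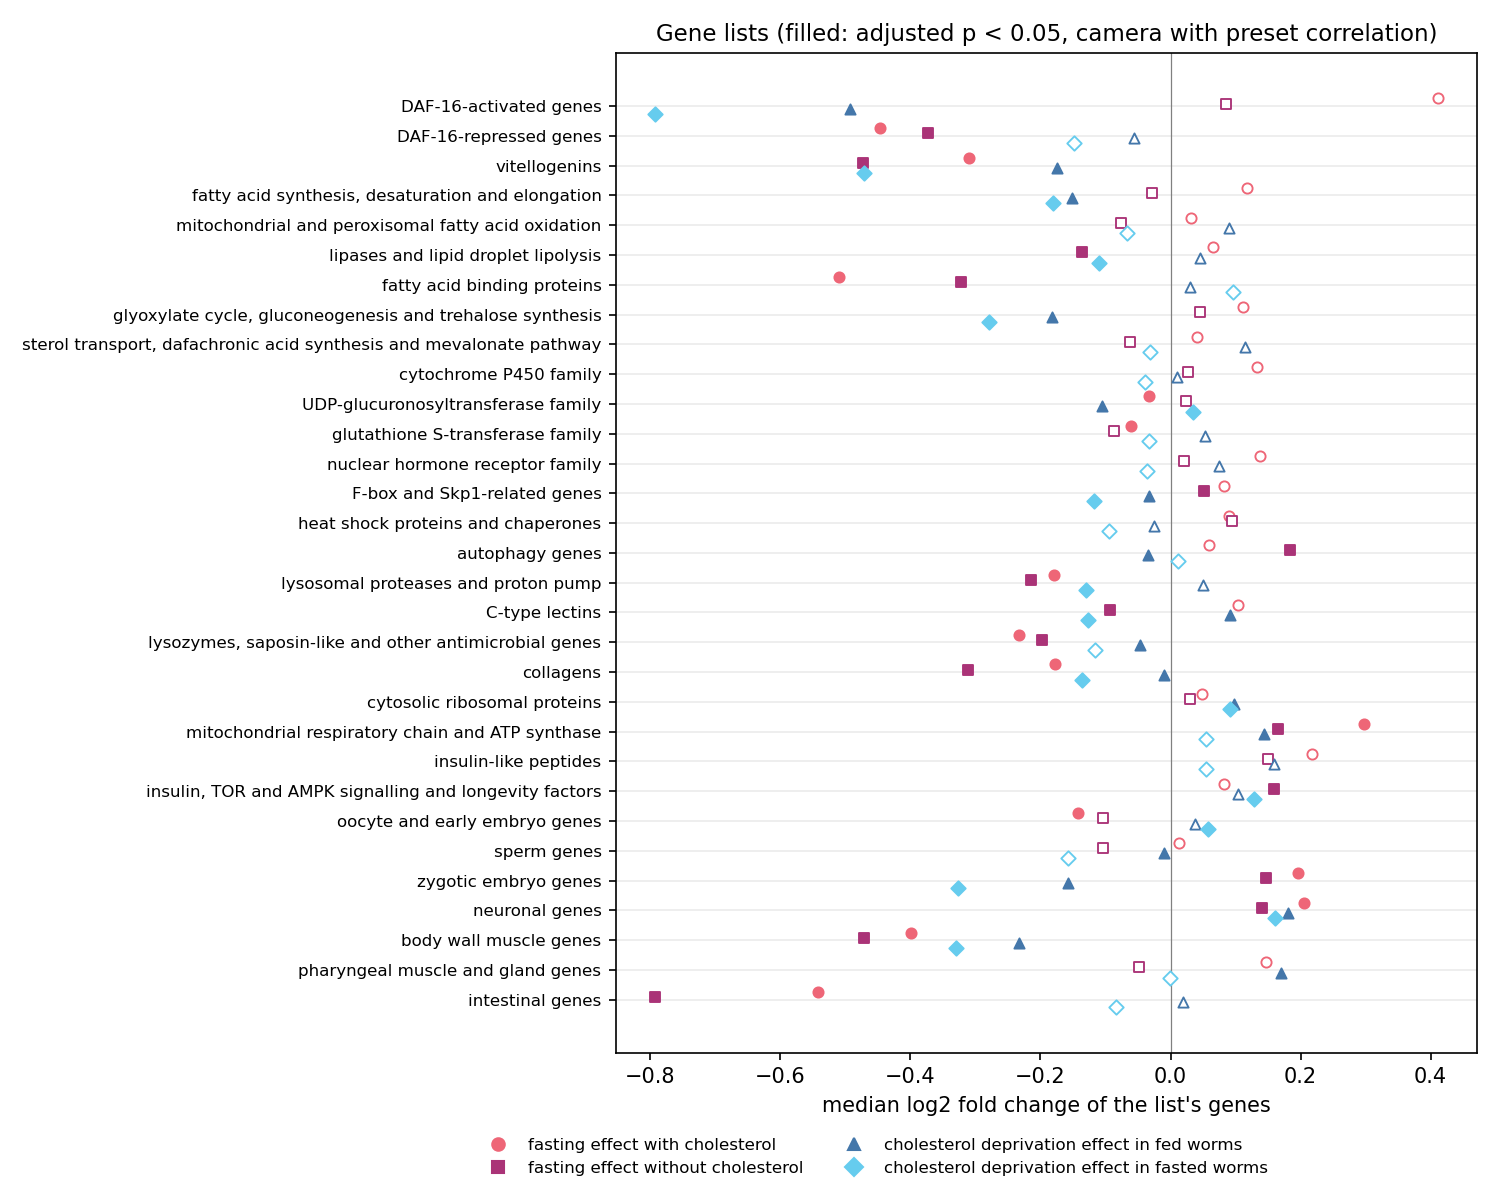
For each of the 31 gene lists, the median log2 change of its genes is plotted for both fasting effects and both deprivation effects, filled where camera with its preset correlation gave an adjusted p under 0.05; 0 lists passed with an estimated correlation. Intestinal markers lie lowest under fasting, at -0.54 with and -0.79 without cholesterol; medians near 0 change sign under other scalings, among them those of UDP-glucuronosyltransferases, glutathione S-transferases, collagens and sperm genes after the bright-set shift, and those of ribosomal proteins and oocyte genes after cyclic loess.

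The fasting response differed between cholesterol states for 22 probe sets, 11 with a higher and 11 with a lower change in deprived worms. Of these, adh-1 (-4.098 ± 0.42, adjusted p = 0.0372), aqp-1 (-3.21 ± 0.28, adjusted p = 0.0184) and acs-2 (-3.18 ± 0.37, adjusted p = 0.0476) rose on fasting in worms given cholesterol and had changes of -0.07, 0.61 and 0.67 in deprived worms, where the fed signal was higher than with cholesterol. A second acs-2 probe set differed by -3.99. The reverse held for cnc-7 (3.70 ± 0.28, adjusted p = 0.0184) and lips-14 (2.78 ± 0.22, adjusted p = 0.0184), which fell with cholesterol and had changes of -0.27 and -0.32 without it. In deprived worms lips-14 lay below the lower quartile of 4.69 whether fed (4.62) or fasted (4.31), where falls are understated. The changes of asp-3 (-2.23 ± 0.21, adjusted p = 0.0282), lys-2 (-1.85 ± 0.19, adjusted p = 0.0392) and lips-11 (-2.55 ± 0.28, adjusted p = 0.0395) were lower in deprived worms, at -2.43, -5.15 and -4.87 against -0.19 (not past the threshold), -3.30 and -2.32 with cholesterol.

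The other genes that the naming rule took with a higher change in deprived worms were srlf-3 (2.06), the antimicrobial peptide gene cnc-4 (1.96), the apical matrix gene noah-1 (1.74, with an uncalled second probe set at 0.43), R07E3.4 (1.54), the tetrahydropterin synthase ptps-1 (1.47), cbl-1 (1.30) and ZK228.4 (1.26). Those with a lower change were F42A10.7 (-2.26), T21H3.1 (-2.11) and clec-62 (-1.83). Second probe sets of cnc-7 (2.44) and cbl-1 (1.65) did not pass. The remaining 3 of the 22, named after their values were seen, were 1 without a gene name (2.04) and probe sets of acs-1 (1.26) and ilys-5 (-1.72) that do not represent their gene; the brighter ones, at 0.89 and -1.54, did not pass. Of the lists, C-type lectins had a lower fasting change in deprived worms (median -0.22, 187 of 220 below 0). The C-type lectin list had a camera adjusted p = 9.69e-06, and adjusted p = 0.904 with an estimated correlation. Over all probe sets the median difference was -0.06, and -0.14 after the bright-set shift, so values below 0 prevailed over the array too. UDP-glucuronosyltransferases had a higher fasting change in deprived worms (median 0.15). The UDP-glucuronosyltransferase list had a camera adjusted p = 1.66e-05, and adjusted p = 0.904 with an estimated correlation. Autophagy genes (median 0.06; camera adjusted p = 0.0305, and adjusted p = 0.976 with an estimated correlation) turned to -0.01 after the bright-set shift, and they and the insulin, TOR and AMPK genes (median 0.08; camera adjusted p = 0.0305, and adjusted p = 0.976 with an estimated correlation) did not pass after cyclic loess (medians 0.05 and 0.09).

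Of the 4 list calls, 2 held without each array in turn. Calls were lost for the other 2, here with the highest adjusted p of each. With the fasted undeprived replicate 1 left out, the signalling (adjusted p = 0.544) list did not pass. With the fasted deprived replicate 2 left out, the autophagy (adjusted p = 0.306) list did not pass. More than 1 array, in the number given, ended the call when left out for autophagy (4), signalling (3).

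The limma interaction count was 0 without replicate 1 of the fed or of the fasted worms given cholesterol (1311 and 1698 probe sets at an unadjusted p under 0.05), 1 without replicate 2 of either or without either fed deprived array, and 8 and 4 without replicate 1 or 2 of the fasted deprived worms. No named gene kept its call through all of these fits. The log2 differences of the 18 named genes stayed at 86.7% to 113% of those from all arrays. Genes chosen for replicates that agree are bound to stay close, so this is no support. In simulations with all 8 arrays, 2-fold differences were recovered in 14% and 4-fold ones in 84% of cases.

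**Figure D3:**
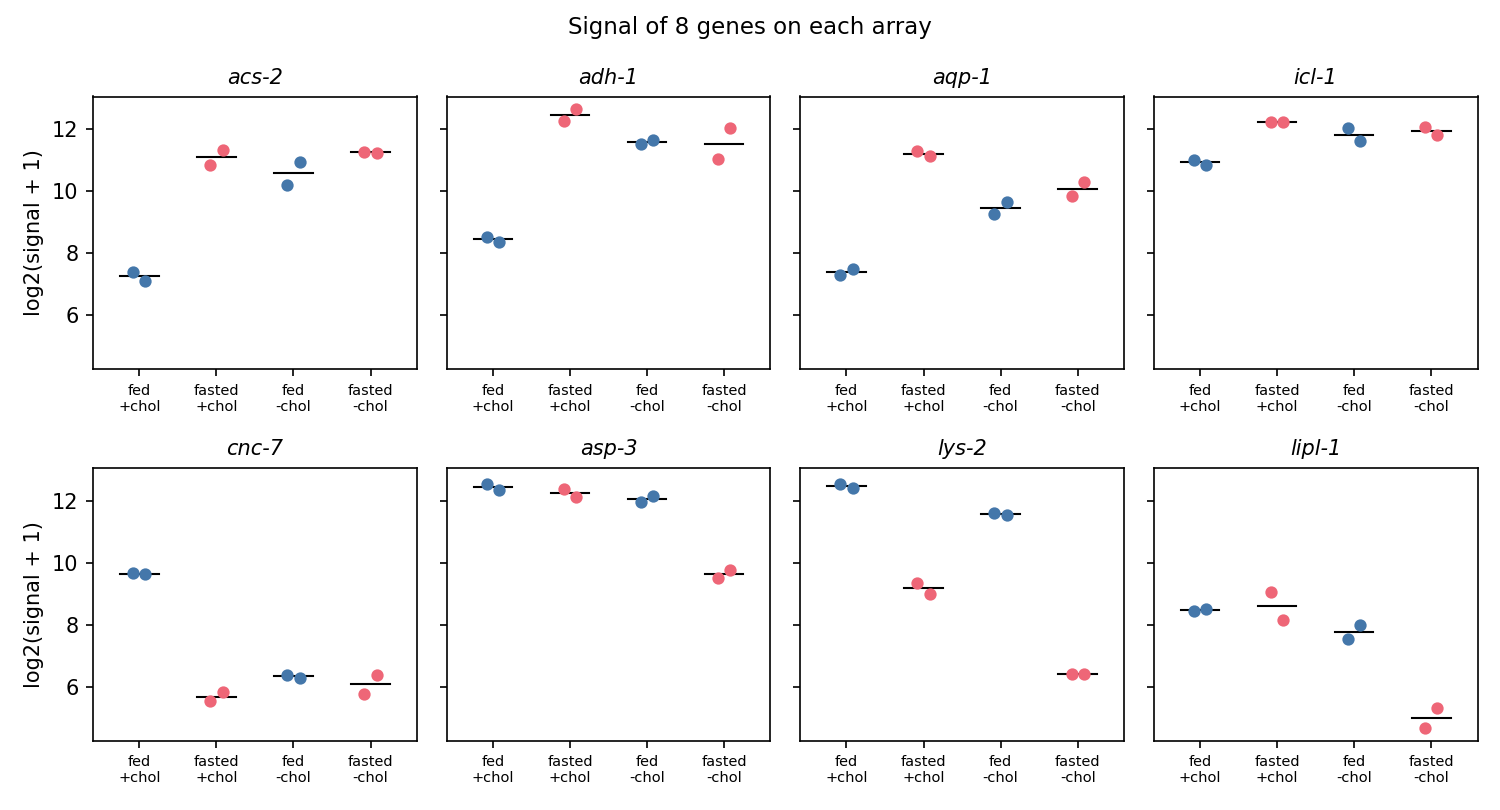
The log2(signal + 1) of 8 genes is drawn for each array, with fed worms in blue, fasted worms in red, and a bar at the mean of the 2 arrays of a group. The genes acs-2, adh-1 and aqp-1 are lowest in fed worms given cholesterol, at means of 7.26, 8.45 and 7.40, while asp-3, lys-2 and lipl-1 are lowest in fasted deprived worms.

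The genes fixed for their link to DAF-16 and to sterols mostly did not pass. The daf-16 transcript changed by 0.31 ± 0.24 on fasting with cholesterol, 0.07 ± 0.24 without it, 0.32 ± 0.24 on deprivation when fed and 0.07 ± 0.24 when fasted. Its targets sod-3 (0.69 ± 0.22 and -0.06 ± 0.22 on fasting with and without cholesterol) and mtl-1 (0.14 ± 0.56 and 0.35 ± 0.56) did not pass either. On fasting, hsp-12.6 changed by 2.66 ± 0.25 with and 1.14 ± 0.25 without cholesterol, icl-1 by 1.31 ± 0.16 and 0.11 ± 0.16, and fat-7 by -2.34 ± 0.30 and -1.20 ± 0.30; their interaction tests did not pass without a block (adjusted p = 0.376, 0.232 and 0.466). The Rieske oxygenase gene daf-36 of dafachronic acid synthesis fell on fasting in deprived worms (-1.20 ± 0.23, adjusted p = 0.0392) and changed by -0.99 ± 0.23 with cholesterol (adjusted p = 0.053); the call in deprived worms was lost in all 8 fits that left out an array, with log2 changes of -1.40 to -0.997. The genes daf-9, daf-12, ncr-1, ncr-2, nhr-49, fat-5, lipl-4, fil-1 and vit-2 did not pass in any of the first 5 contrasts with limma. Of 29 sterol and mevalonate genes, chup-1 rose on fasting with cholesterol (0.68 ± 0.12) and the sterol methyltransferase gene strm-1 was higher in fasted deprived worms (0.98 ± 0.14); that list did not pass in any contrast, with camera adjusted p from 0.234 to 0.984 over the 7 contrasts.

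Averaged over cholesterol states, with 4 arrays against 4, fasting moved 2398 probe sets, 1240 higher and 1158 lower, and averaged over feeding states, deprivation moved 925, 457 higher and 468 lower. Of those moved by fasting, 559 changed at least 2-fold, of which 459 were lower; of those moved by deprivation, 251 did, of which 139 were lower. The 2 average effects correlated at r = 0.10 across probe sets, with a Spearman correlation of -0.06. The limma count for fasting was 1379 and 1209 without replicate 1 or 2 of the fed undeprived worms, 1510 and 1155 without replicate 1 or 2 of the fed deprived worms, 1405 without replicate 1 of the fasted undeprived worms and 1482 without replicate 2 of the fasted deprived worms. The count for deprivation was 281 and 494 without replicate 1 or 2 of the fed undeprived worms, 333 and 541 of the fasted undeprived worms, 493 and 369 of the fed deprived worms and 470 without replicate 1 of the fasted deprived worms, and the share of higher calls under fasting, 51.7%, was 64.6% after the bright-set shift.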

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

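Of the tests in this part, the share of _s_at and _x_at probe sets and the comparison of the cholesterol difference in fed and in fasted worms were chosen after the result was seen.

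What drew attention here is a fasting effect that differed between the cholesterol states by a test of the difference itself, which held for 22 probe sets. The log2 difference, deprived minus undeprived, was 3.70 for cnc-7, 2.78 for lips-14, 2.06 for srlf-3, 1.96 for cnc-4, 1.74 for noah-1, 1.54 for R07E3.4, 1.47 for ptps-1, 1.30 for cbl-1 and 1.26 for ZK228.4. It was -4.098 for adh-1, -3.21 for aqp-1, -3.18 for acs-2, -2.55 for lips-11, -2.26 for F42A10.7, -2.23 for asp-3, -2.11 for T21H3.1, -1.85 for lys-2 and -1.83 for clec-62. Of gene lists, the median difference was -0.22 for C-type lectins, 0.15 for UDP-glucuronosyltransferases, 0.0645 for autophagy genes and 0.0824 for insulin, TOR and AMPK genes (adjusted p of 0.904 to 0.976 with an estimated correlation).

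The interaction pattern holds genes that deprivation of fed worms and fasting of undeprived worms moved the same way (acs-2, adh-1, cnc-7 and lips-14) and genes with their lowest mean in fasted deprived worms (asp-3 and lys-2). A ceiling of the array is argued against: 2 of the 22 probe sets had a highest group mean above 12.73, the 99th percentile of all values; at the floor, lips-14 and the probe set without a gene name had lowest means of 4.31 and 3.63, below the lower quartile of 4.69, and their sizes stay open. An over 2-fold excess of probe sets that match several transcripts is argued against, since 18.2% of the 22 had such names, against 29.8% of all probe sets. The Clopper-Pearson interval of 5.19% to 40.3% includes 29.8%, so a smaller excess stays open. Cross-hybridisation of other probe sets was not examined. A candidate explanation is that deprivation had already moved these genes in fed worms and left less for fasting to change, but it stays open: the larger cholesterol difference lay in fed worms for 12 of the 22, a count that ignores direction and includes lips-11, which deprivation raised in fed worms and fasting lowered. A biological difference in the response is likewise open and untested.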

How the results depend on the processing

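All alternatives were planned; none was added after the data were seen. Of 315 called values of single named genes, those still called numbered 315 with the replicate block, 297 after cyclic loess, 302 after the bright-set shift, 308 with trend and robust settings, 303 with array weights, 243 with log2(signal + 16), 209 of 297 with the compared groups alone, 280 of 289 without dim probe sets and 219 of 219 without _s_at and _x_at sets. When an array was left out, 183 to 247 were still called. None turned its sign under these settings. Of 67 list calls in the first 5 contrasts, 52 to 67 were kept under each setting except an estimated correlation, which kept 0. Signs of uncalled values changed 165 times for lists and 33 times for genes. Dim signal limits the folds, since log2(signal + 1) and log2(signal + 16) differ most there.

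The labels do not say that replicate numbers share a day. Deviations of same-numbered arrays correlated at 0.22 to 0.53 in the 6 comparisons of groups, and the third principal component (12.3%) separated the numbers. With the replicate block, counts were 3106 and 1730 (fasting with and without cholesterol), 988 and 785 (deprivation in fed and fasted worms), 115 (interaction), 4409 and 2067 (average fasting and deprivation), and all calls without the block were among them. The interaction of icl-1 passed with the block (adjusted p = 0.0305), and those of hsp-12.6 and fat-7 did not (0.150 and 0.225).

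In the same order, an adjusted p under 0.1 gave 2418, 1149, 568, 446, 35, 3640 and 1468. Without _s_at and _x_at sets, fewer being tested, the fasting counts were 721, 426 and 1470 (average), and the correlation of the average effects was 0.067 against 0.096. A 2-fold minimum left 550, 408, 559 (average fasting) and 251 (average deprivation). Trend and robust settings gave 431 (deprivation when fed) and 42 (interaction), and log2(signal + 16) gave 177 and 7. With the compared groups alone, fewer arrays estimated the spread and counts were 739, 333 and 78 (deprivation when fasted). The bright-set shift changed the higher and lower calls of fasting with cholesterol from 457 and 707 to 921 and 591, and of average fasting from 1240 and 1158 to 1760 and 964, while the median of all probe sets in the first moved from 0.08 to 0.17.

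Leaving out each array in turn gave ranges of 381 to 1153, 258 to 582, 25 to 284, 61 to 157, 0 to 8, 1155 to 2073 and 281 to 794 in that order. The correlation of the average effects ranged from 0.019 to 0.158, and the difference in response size from -0.174 to 0.073, with a fry p of 0.213 over all arrays, 0.0137 without replicate 2 and 0.29 without replicate 1 of the fasted deprived worms. The correlation of the fasting effects (0.638 to 0.727) and the number of list calls (60 to 67) stayed within 1.5 times, although 27 of the 67 calls were lost without at least 1 array. Ribosomal proteins reversed after cyclic loess, to -0.0743 on fasting with cholesterol (from 0.05, not called; adjusted p = 0.0245) and -0.0502 on deprivation when fed. Body wall muscle genes on deprivation when fasted reversed in camera's direction without _s_at and _x_at sets (median -0.0396). Collagens there ranged from -0.295 to 0.026 over the left-out arrays. Where no construction is named, the cause was not tested.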

Other observations

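Of the tests in this part, those of the intestinal share, of other tissues, of RNA degradation and of germline RNA were chosen after the result was seen.

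Averaged over cholesterol states, fasting moved 2398 of 22548 probe sets, 1240 of them higher. Of 329 F-box and Skp1-related genes, 31 rose and 13 fell (camera adjusted p = 0.0502, not past the threshold, 0.0496 after cyclic loess and 0.0426 after the bright-set shift, and adjusted p = 0.461 with an estimated correlation), and of 259 nuclear hormone receptors 11 rose and 1 fell (camera adjusted p = 0.0243, and adjusted p = 0.405 with an estimated correlation). Neuronal genes rose in 21 and fell in 7 of 106 cases (camera adjusted p = 0.000332, and adjusted p = 0.479 with an estimated correlation), and 5 of 28 autophagy genes rose (camera adjusted p = 0.0448, and adjusted p = 0.405 with an estimated correlation). Heat shock proteins had 5 rises and 2 falls among 21 (list adjusted p = 0.742), and cytochrome P450 genes 8 and 10 among 73 (list adjusted p = 0.815). For C-type lectins, 28 falls and 4 rises gave a test downwards (adjusted p = 0.0245, and adjusted p = 0.479 with an estimated correlation) although the median was 0.01, and -0.03 after cyclic loess.

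Averaged over feeding states, deprivation lowered 8 of 20 DAF-16-activated genes and raised 0 (median -0.53). The DAF-16-activated list had a camera adjusted p = 2.2e-05, and adjusted p = 0.43 with an estimated correlation. Over the array, 457 of 22548 probe sets were higher and 468 lower. Of 24 fatty acid synthesis genes 0 rose and 6 fell (camera adjusted p = 0.00203, and adjusted p = 0.37 with an estimated correlation), and of 5 vitellogenins 0 rose and 3 fell (camera adjusted p = 0.00203, and adjusted p = 0.37 with an estimated correlation). Of 45 zygotic embryo genes 0 rose and 5 fell (camera adjusted p = 3.14e-08, and adjusted p = 0.37 with an estimated correlation), of 106 neuronal genes 7 rose and 0 fell (camera adjusted p = 6.61e-07, and adjusted p = 0.436 with an estimated correlation), and of 72 pharyngeal genes 5 rose and 0 fell (camera adjusted p = 0.017, and adjusted p = 0.436 with an estimated correlation). Insulin-like peptides moved up as a list (median 0.10; camera adjusted p = 0.0353, and adjusted p = 0.436 with an estimated correlation) with 1 of 24 risen and 0 fallen.

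In the lysosomal, lipase and antimicrobial lists, 14 genes fell with deprivation in fasted worms, and these 14, selected for having fallen, had a median change of -1.72; the antimicrobial list as a whole did not pass (camera adjusted p = 0.272). A smaller share of intestine in the RNA is argued against as the whole of a fall of that size. The fixed intestinal markers had a median of -0.083 (95% bootstrap interval over genes, taken as independent, -0.40 to 0.17). These are 26 genes, 9 of them also in the lysosomal list. A smaller loss of intestinal share, within that interval, stays open as a part of the fall, since selection enlarges the median of the 14. A larger share of all other tissues means a smaller share of intestine, so the same intestinal median argues against it for a fall of this size. The other tissue medians alone do not decide it. They moved apart by 0.49, at 0.16 for neuronal, 0.06 for oocyte and -0.33 for body wall muscle genes. Without _s_at and _x_at sets the muscle median was -0.04 (95% interval -0.34 to 0.14), which overlaps the neuronal interval of 0.06 to 0.29. A lowered expression of these genes in the intestine may also be at work and was not tested.

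The collagen, muscle, intestinal and antimicrobial lists had medians below 0 after fasting at both cholesterol states, and their calls were lost with an estimated correlation (adjusted p = 0.472, 0.472, 0.227 and 0.128 with cholesterol, 0.297, 0.297, 0.118 and 0.118 without). RNA degradation in fasted samples is argued against: the difference between 3' and 5' signal of 4 control transcripts changed most for ubiquitin, by 0.095 log2. The range of 2 standard errors either side was 0.0092 to 0.18, and an exact test of fasted against fed arrays gave p = 0.0857. Replicate 1 of the fasted deprived worms stood apart for actin and catalase (1.99 and 2.37, against at most 1.87 and 2.06 in the other arrays), and without it the medians of these lists without cholesterol were -0.44, -0.67, -0.87 and -0.21. A dilution by more germline and egg RNA stays open: the 48 oocyte and early embryo genes had a median average fasting change of -0.106, but zygotic embryo genes had 0.27. The 95% bootstrap interval of the former, over genes taken as independent, was -0.21 to -0.018. A change in the size of tissues relative to each other may also underlie the pattern and was not examined.

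A hypothesis tested was that deprivation of fed worms and fasting of undeprived worms move genes alike. Their effects share the fed arrays with cholesterol: r was 0.32 across probe sets, against 0.50 in 100 simulations without effects, but the covariance was 0.0476 against 0.0149 simulated. They had 46 higher calls in common, against 2.35 for independent lists, 76 lower, against 4.92, and 14 in opposite directions. The simulations had 0 common calls, but without effects almost no probe set could pass, so they set no expectation for these counts. Part of the excess over independent lists may come from the shared arrays and from the shared estimate of the spread. With the arrays of the 2 effects kept apart, r was 0.201 and 0.231, a positive result for the hypothesis as stated. Both effects still have the fed worms given cholesterol as their reference, so anything that sets this group apart would also give a positive r. The average fasting and average deprivation effects, which do not rest on that 1 reference group, correlated at r = 0.10 (Spearman -0.06). The result therefore does not show that deprivation and fasting act alike in general.

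Another hypothesis was that the rise of ttr-21, ttr-23 and ttr-29 in fasted deprived worms belongs to the whole transthyretin-related family. The result was negative for a rise of the whole family: of 40 genes measured, the other 37 had a median of -0.0136 (camera p = 0.215, and p = 0.661 with an estimated correlation). The 95% bootstrap interval over genes, taken as independent, was -0.11 to 0.13, too narrow given an estimated correlation of 0.23. Of these 37, 3 rose and 2 fell, a larger share each way than over the array, where 155 of 22548 probe sets rose and 94 fell.

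The averages were also set against other splits of the 8 arrays, in a plain comparison of 4 against 4. The fasting split gave 1312 probe sets and 1 of the 35 splits reached that number, itself, with 65 as the highest other. This share counts all 35 splits as equally likely, but deviations of same-numbered arrays correlated at 0.22 to 0.53. The share alone therefore cannot exclude chance. The cholesterol split gave 65, which 2 of the 35 reached, itself and the fasting split with 1312, so this test did not exclude chance. The fasting split follows a factor of the design, a structure of the samples that fixed this count, so the count does not argue for chance either. Among the other 33 splits the highest was 63, by replicate number. The 2 effects of each factor share no array, but they share 1 estimate of the spread per probe set. Calls can therefore coincide more often than in independent lists, and those numbers are no measure of chance here. The direction of a change does not depend on that spread. That most common calls had the same direction argues against chance for both factors, for the probe sets called in common. The 2 fasting responses had 100 higher and 323 lower such calls, against 4.52 and 13.6 for independent lists, and 4 in opposite directions. The 2 deprivation effects had 59 and 13, against 0.797 and 0.655, and 3 in opposite directions.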
